A study of Mus musculus with 6 samples.

How the data were processed

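The data are RNA-seq read counts per gene from lung fibroblasts of male C57BL/6J mice aged 9 to 11 weeks, sorted by flow cytometry for PDGFRA, the platelet-derived growth factor receptor alpha that marks most lung fibroblasts. Per the labels' protocols, 9 mice breathed room air and 9 mice breathed 10% CO2 for 10 days. The cells of 3 mice made up each replicate, giving 3 libraries per group. The libraries of a group are therefore separate pools of animals, and the spread between them includes differences between pools but averages over the mice inside each pool. Per the labels, RNA was extracted with a column kit, libraries were made with NEBNext Ultra RNA and sequenced on a NextSeq 500, and 5000000 to 7500000 aligned reads per sample are named as the average depth.

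The deposited values are raw counts for 43430 Ensembl gene IDs in 6 columns, whole numbers with no normalization. Per the submitters' processing notes, bcl2fastq 2.17.1.14, FastQC, TopHat2 2.1.0, HTSeq and the mm10 build were used, without their roles or order. The annotation release, the strand setting of the counting and any read filter are not given in the sources used here. Without a known strand setting, reads of a gene and of an overlapping gene on the other strand may have been mixed or dropped, so exonic overlaps of the named genes were looked up and are stated beside the genes they concern. The deposited counts come as a single table whose columns carry the group in their names but sample numbers that differ from those of the sample titles. Each column was therefore assigned to its group and not to a particular sample, and the columns are called M1 to M3 (room air) and M4 to M6 (hypercapnia). No other columns of values were present. Gene names and positions came from GENCODE M21, on the build the submitters name, which gave a symbol for 42462 of the IDs. IDs without a symbol held between 0.0982% and 0.123% of the counts of a library.

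Total counts per library ran from 8999780 to 10198336, above the aligned reads that the labels name as the average depth, and the sources used here do not explain the difference. At this depth 3 counts correspond to between 0.294 and 0.333 CPM, that is, counts scaled to a common library size. The CPM values, computed here from the deposited counts with TMM factors, are given as mean ± SD over 3 libraries. The test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3), two-sided, on all 6 libraries with the group as the only term and 4 residual degrees of freedom. TMM factors lay between 0.943 and 1.05, and edgeR's default filter by group, with its minimum count of 10, kept 13005 genes. The p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called changed, higher (rose) or lower (fell) in hypercapnia. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic. The median log2 fold change over all tested genes was 0.01.

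Before the data were examined, 51 gene lists were fixed for signalling pathways, fibroblast subtypes, other lung cell types, extracellular matrix, metabolism, stress, immune genes, acid-base handling and sample handling. The 47 lists with at least 3 tested genes were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, against all other tested genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, a rotation test of each list on its own, in a single direction or, where said, in either direction, were run as alternatives. The genes named in the text follow a rule fixed at the same time. It takes the 12 largest positive and the 12 largest negative log2 fold changes among changed genes with a mean of at least 5 CPM and no overlap between groups, leaving out unnamed gene models. It adds every Wnt ligand past the filter, up to 4 members with the smallest p in each list, and Pdgfra, Col1a1, Ptprc, Pecam1 and Epcam as checks of the sort. In all, 66 higher and 87 lower genes qualified for the first part. Genes named outside the rule are marked as chosen after their values were seen.

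The tests were first run on simulated counts with the means, spread and library sizes of this comparison. Of the genes changed by known factors among 12895 simulated genes, 18.4% were called at 1.5-fold, 51% at 2-fold, 72% at 3-fold and 88% at 4-fold, and 8.8% of the calls were false. Changes under about 2-fold were therefore often missed at this number of libraries. In that simulation 0 of 50 random lists reached p under 0.05. Its genes were drawn independently of each other, so it could not check list calls where genes vary together. The endothelial list, for example, had an estimated correlation of 0.916. Replicate counts were compared by a chi-square over genes. The chi-square per degree of freedom was at least 13.1 for every pair of libraries, so no library was a repeat of another.

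Alternatives fixed before the data were examined were other normalization factors, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, robust dispersion shrinkage, other thresholds, and leaving out each library in turn. After the data were seen, the mean level of the endothelial marker list and that of the immediate early gene list were each added as a covariate, and the fit was repeated without the room air library lowest and the hypercapnia library highest in endothelial markers (M3 and M4). The labels give no batch, day or hour of collection. A difference between the groups in any of these could therefore not be separated from hypercapnia, for any gene.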

Results

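Gene expression was measured by RNA-seq in PDGFRA-sorted mouse lung fibroblasts after 10 days in 10% CO2 (hypercapnia, an excess of CO2 in the blood) or in room air, with 3 libraries per group and the cells of 3 mice in each library. Total counts were 8999780, 9759770 and 9292923 in the room air libraries M1, M2 and M3, and 9009124, 9744259 and 10198336 in the hypercapnia libraries M4, M5 and M6. The sorted receptor was abundant in every library. Pdgfra stood at 3562 ± 209 CPM (SD, n = 3) in room air and 2971 ± 419 CPM in hypercapnia, with an edgeR log2 fold change of -0.26 ± 0.11 (SE) and an adjusted p of 0.383. Col1a1, the main chain of type I collagen, stood at 5078 ± 285 and 4942 ± 479 CPM. Ptprc, the pan-leukocyte marker CD45, had 2 counts in all 6 libraries together. Without TMM factors, the epithelial marker Epcam ran from 0 to 2.11 CPM over the libraries. Sftpc, a marker of alveolar type 2 cells, ran from 49.7 to 198 CPM.

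The comparison of hypercapnia with room air asks how prolonged high CO2 alters the fibroblast transcriptome, and in particular, by the title of the series, the production of Wnt ligands. In the hypercapnia libraries the circadian clock genes Per2 and Per3 were about 3-fold higher while their activators Npas2 and Arntl were nearly lost. The growth factor binding protein gene Igfbp3, elastin (Eln) and the matrix genes Spon2 and Col5a3 were lower, and Ltbp2, which encodes a microfibril-associated protein, was higher. By edgeR's quasi-likelihood test 159 of 13005 genes changed, 68 of them higher and 91 lower, and in all 159 the libraries of the groups did not overlap. Over all tested genes 18% had no overlap, where chance gives 10%. Without composition factors the split was 97 higher and 75 lower of 172. The count fell to 24 without M2, to 27 without M5 and to 42 without M6.

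Among the genes with the largest increases were Rgs9, a regulator of G protein signalling (2.05 ± 0.32 on the log2 scale, SE, 3.29 to 13.6 CPM), the transcription factor Sox11 (1.95 ± 0.37), the chemokine receptor Cxcr4 (1.68 ± 0.27) and Ccn4, a secreted matricellular protein (1.46 ± 0.21, 16.6 to 45.5 CPM). Mthfd1l, an enzyme of mitochondrial folate metabolism, Exoc3l, Wipf3 and Megf6 rose by between 1.62 and 1.70. Stab1, a scavenger receptor of sinusoidal endothelium and macrophages, and Esm1, a proteoglycan secreted by endothelial cells, rose by 1.65 and 1.77. The mean level of the endothelial marker list was also higher in the hypercapnia libraries, at 7.32 ± 0.33 against 6.29 ± 0.94 log2 CPM (SD, n = 3). With that level as a covariate, chosen after seeing the data, 24 of the 68 higher and 66 of the 91 lower genes were still called, and the 68 and the 91 all kept their direction. The calls of Megf6 (1.62 ± 0.33 before and 0.82 ± 0.24 after), Mthfd1l (1.70 ± 0.30 and 1.11 ± 0.30), Stab1 (1.65 ± 0.31 and 1.04 ± 0.26) and Esm1 (1.77 ± 0.35 and 1.1 ± 0.37) were lost there with smaller log2 fold changes. Those of Cxcr4 (1.57 ± 0.36 after, adjusted p = 0.0507) and Sox11 (1.67 ± 0.46) were lost with log2 fold changes that moved by less than their SE while the SE widened. Without M5 the calls of these 10 genes were all lost (adjusted p of 0.0558 for Ccn4, 0.0743 for Wipf3, 0.0934 for Rgs9, 0.0963 for Exoc3l, 0.108 for Cxcr4, 0.141 for Mthfd1l, 0.155 for Stab1, 0.164 for Megf6, 0.187 for Sox11 and 0.199 for Esm1). All but Wipf3 were lost without M6 (0.0647 for Rgs9 to 0.135 for Sox11), and all but Ccn4 and Sox11 without M2 (0.0563 for Mthfd1l to 0.222 for Stab1). Esm1 (0.0598), Mthfd1l (0.0598), Megf6 (0.051) and Sox11 (0.0861) were lost without M1, Sox11 (0.0569) without M3, and Esm1 (0.0654), Mthfd1l (0.0513), Megf6 (0.0993) and Stab1 (0.0539) without M4. Stab1 was also lost with robust dispersion (0.133).

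Igfbp3 fell from 1163 ± 94.5 to 327 ± 59.1 CPM (log2 fold change -1.83 ± 0.14, adjusted p = 0.000642). The gene, ENSMUSG00000020427, lies on chromosome 11 from 7206086 to 7213923. Spon2, a secreted matrix protein, fell from 199 ± 59.0 to 35.1 ± 9.73 CPM (-2.50 ± 0.25). Colq, the collagen tail of acetylcholinesterase, and Gja5, which encodes the gap junction protein connexin 40, had log2 fold changes of -1.52 ± 0.13 and -1.41 ± 0.15. Serpina3c, Clmp and the transcription factor Creb3l1 had log2 fold changes of -1.51, -1.51 and -1.66. Camk2a, a calcium-dependent kinase, fell from 17.3 to 3.61 CPM. Without M2 the calls of Camk2a (adjusted p = 0.0611) and Creb3l1 (0.052) were lost. In the exons of Clmp, 10.1% of the bases overlap another gene model, and counts there cannot be assigned to either without the strand setting.

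**Figure D1:**
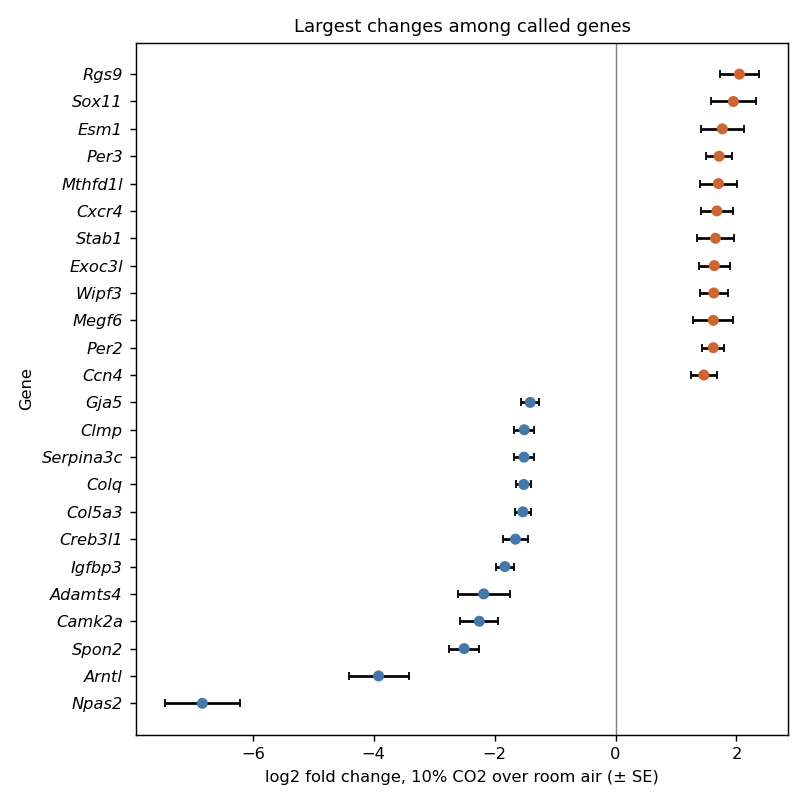
Log2 fold changes (x axis, hypercapnia over room air, points with SE bars from the edgeR fit, 3 libraries per group) of the 12 largest increases (orange) and 12 largest decreases (blue) among changed genes, 1 gene per line. The clock genes Npas2 and Arntl lie farthest below 0, at -6.83 and -3.92.

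The circadian clock list moved in both directions. Of 17 measured members, 5 rose, 4 fell and 8 did not pass the test. Npas2 and Arntl (Bmal1), partner transcription factors that activate clock targets, were nearly absent in hypercapnia. Npas2, ENSMUSG00000026077 on chromosome 1 from 39193731 to 39363236, had 363 counts in the room air libraries together and 3 in hypercapnia. The ratio per effective library size was 131, with an exact 95% interval of 44.4 to 636 that covers counting error only. Arntl, on chromosome 7 from 113207465 to 113314126, fell from 33.3 ± 8.71 to 2.27 ± 2.06 CPM (SD, n = 3, log2 fold change -3.92 ± 0.50, edgeR adjusted p = 0.00582). Per2, a repressor of the clock on chromosome 1 from 91415982 to 91459324, rose from 45.3 ± 12.5 to 139 ± 11.7 CPM (1.62 ± 0.18, adjusted p = 0.00326), and Per3 rose by 1.71 ± 0.21. Chosen after their values were seen, Hlf (0.97), Tef (0.89) and Cry1 (1.15) also rose, and Nr1d1 (-1.25) and Clock (-0.84) fell. Camera called the list higher (adjusted p = 0.0442), with a median log2 fold change of 0.50 but a mean of -0.15 over its genes. The call was lost with an estimated correlation (adjusted p = 0.671), and without M2, M3, M4 or M6 (adjusted p of 0.104, 0.215, 0.0975 and 0.103), with the endothelial covariate (0.688) and without M3 and M4 (0.341). It was also lost by fry (0.27), by camera on ranks (0.103) and with the stricter filter (0.0532). Without M2, the calls of 7 of the 9 changed clock genes were lost: Arntl (adjusted p = 0.052), Per3 (0.0588), Cry1 (0.105), Hlf (0.137), Tef (0.145), Clock (0.183) and Nr1d1 (0.185). In the same order, their log2 fold changes there were -3.98, 1.59, 1.25, 0.92, 0.87, -0.86 and -1.18. Each had moved by less than its SE. Without M5, Hlf (0.0886), Tef (0.106), Nr1d1 (0.119), Cry1 (0.141) and Clock (0.157) were lost. Some of these 5 were also lost without M1 (Cry1 0.0691, Nr1d1 0.055, Clock 0.055), M3 (Clock 0.0672), M4 (Cry1 0.0539) or M6 (Hlf 0.0647, Tef 0.0872, Clock 0.0961), while Npas2 and Per2 kept their calls without any 1 library. Nr1d1 was also lost with robust dispersion (0.129).

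**Figure D2:**
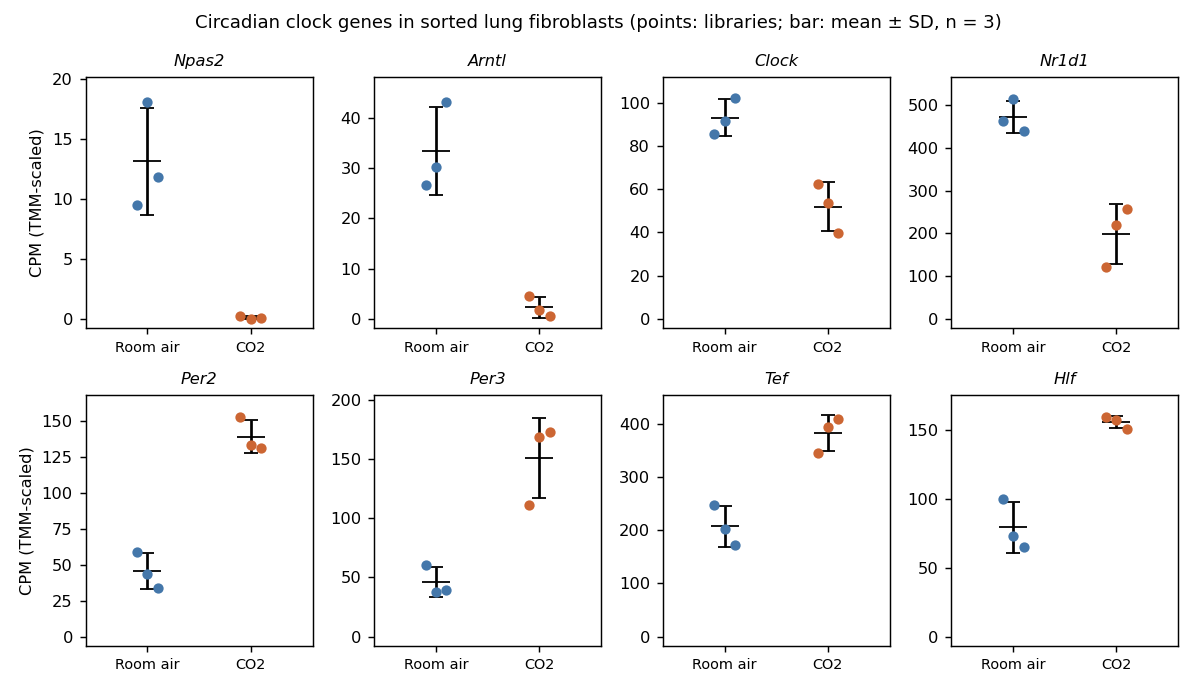
TMM-scaled CPM (y axis) of 8 circadian clock genes in each room air (blue) and hypercapnia (orange) library, with mean ± SD of 3 libraries. Npas2, Arntl, Clock and Nr1d1 were lower and Per2, Per3, Tef and Hlf higher in every hypercapnia library than in every room air library.

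Of the 19 Wnt ligands, secreted signals of epithelial progenitor niches, 8 were measured above the filter. Wnt5a, a ligand of mainly beta-catenin-independent signalling, rose from 81.8 ± 7.95 to 135 ± 25.4 CPM (SD, n = 3). Its log2 fold change was 0.72 ± 0.15 with an edgeR adjusted p of 0.0467, and it was the only ligand past the threshold over all genes. Wnt5a, ENSMUSG00000021994, lies on chromosome 14 from 28504750 to 28527448. Wnt2b stood at 10.6 ± 2.38 and 21 ± 4.75 CPM (0.99 ± 0.24, adjusted p = 0.0949), and Wnt2, the most abundant ligand in room air, at 120 ± 3.09 and 92.6 ± 8.72 CPM (-0.37 ± 0.11, adjusted p = 0.166). Adjusted over the list alone, 3 ligands passed: Wnt5a and Wnt2b higher, and Wnt2 lower. Wnt2 is also a member of the alveolar fibroblast marker list, whose median log2 fold change was -0.353. Its fall therefore cannot be told apart from that of the alveolar markers. The title of the study names Wnt production in these samples, so this count is not independent evidence. Wnt11 (0.67 ± 0.34) and Wnt10b (1.05 ± 0.68) did not pass, and neither did Wnt9a (-0.19 ± 0.15), Wnt5b (-0.06 ± 0.25) and Wnt4 (-0.04 ± 0.19), of which Wnt5b and Wnt4 turned to 0.01 and 0.03 without composition factors. Camera did not call the ligands as a list (adjusted p = 0.229, and 0.707 with an estimated correlation), and fry for changes in either direction gave an adjusted p of 0.0114. The call of Wnt5a was lost without M1 (adjusted p = 0.0835), M2 (0.21), M3 (0.0923), M5 (0.199) or M6 (0.13), and with the endothelial marker level as a covariate (0.117, log2 fold change 0.61 ± 0.18, where its SE widened), with log2 fold changes of 0.56 to 0.83 across all settings.

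**Figure D3:**
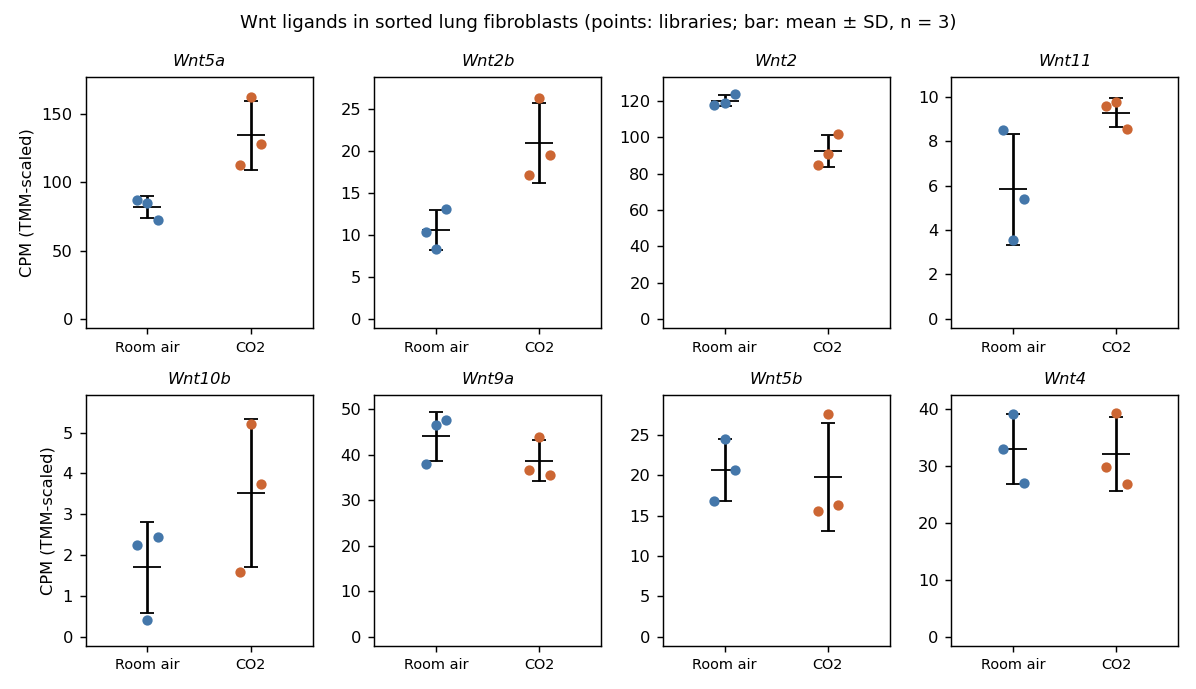
TMM-scaled CPM (y axis) of the 8 Wnt ligands past the count filter in each room air (blue) and hypercapnia (orange) library, with mean ± SD of 3 libraries. The groups do not overlap for Wnt5a, Wnt2b, Wnt2 and Wnt11, of which Wnt5a alone passed the threshold over all genes.

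Few other genes of the Wnt pathway passed the threshold over all genes. Of 16 measured beta-catenin target genes only Ccn4 rose, and Axin2, a direct target of the pathway, stood at 98.7 ± 2.88 and 99.4 ± 8.24 CPM (0.01 ± 0.11, adjusted p = 0.985). Of 14 secreted modulators only Sfrp4, a soluble Frizzled-related protein, rose (1.19 ± 0.20, 8.97 to 20.4 CPM). The call of Sfrp4 was lost without M1 (adjusted p = 0.0567), M2 (0.1), M4 (0.0517), M5 (0.0915) or M6 (0.111), and that of Ccn4 without M5 (0.0558) or M6 (0.0647). None of 17 receptors and co-receptors passed over all genes, and 3 passed when adjusted over the list alone. Camera adjusted p was 0.301 for the targets, 0.91 for the modulators and 0.866 for the receptors. By fry for changes in either direction it was 0.00819, 0.000433 and 0.00777, a test that called 28 of the 47 lists. Of 18 measured growth factors of the alveolar niche, 0 passed over all genes, among them Fgf7 (-0.27 ± 0.11), Hgf (-0.24 ± 0.11) and Tgfa (-1.0 ± 0.22, adjusted p = 0.0682).

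Of 16 measured elastic fibre genes 2 fell and 1 rose. Eln, on chromosome 5 from 134702593 to 134747323, fell from 2135 ± 328 to 824 ± 158 CPM (-1.37 ± 0.16, adjusted p = 0.00365), and Fbn1, the main microfibril protein, fell by 0.54 on the log2 scale, with 20.1% of its exonic bases shared with an unnamed gene model. The call of Fbn1 was lost without M1 (adjusted p = 0.0924), M2 (0.215), M3 (0.0613), M5 (0.199) or M6 (0.143). Ltbp2, on chromosome 12 from 84783212 to 84876532, rose from 146 ± 15.2 to 393 ± 29.8 CPM (1.42 ± 0.12, adjusted p = 0.000642), with 9.34% of its exonic bases shared. The other 13 members did not pass, and camera did not call the list (adjusted p = 0.336). Of the 24 measured members of the fixed list of fibrillar and network collagens only Col5a3 changed (-1.53 ± 0.13, 80.6 to 27.9 CPM). Outside that list, and chosen after its values were seen, the collagen gene Col27a1 rose (0.55 ± 0.11, adjusted p = 0.0468), a call lost without each of the libraries M1 to M6 (0.0567 to 0.259), with RLE factors (0.0524), with the endothelial covariate (0.108) and without M3 and M4 (0.0684). Also outside it and chosen after their values were seen, Col23a1 (-0.59 ± 0.12, adjusted p = 0.0442) and Col13a1 (-0.89 ± 0.12) fell. Col23a1 was still called with the endothelial covariate (0.0387) and was not followed with libraries left out. Of 23 matrix proteases and inhibitors, Mmp14, a membrane-bound collagenase, fell from 360 ± 11.6 to 188 ± 23 CPM (-0.94 ± 0.12), Adamts4 fell from 9.91 to 2.20 CPM and 21 did not pass. Neither was called without M2 (adjusted p = 0.0575 for Mmp14 and 0.231 for Adamts4), and the call of Adamts4 was also lost without M1 (0.0835), M5 (0.188) or M6 (0.157) and by limma-voom (0.0532). The protease list was called lower (camera adjusted p = 0.0283). That call was lost with an estimated correlation (adjusted p = 0.671) and without M2, M4 or M6 (adjusted p of 0.096, 0.0584 and 0.0526), and with the endothelial covariate (0.0603). It was also lost by fry (0.224), by camera on ranks (0.201) and without M3 and M4 (0.0519).

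Markers of alveolar fibroblasts, the lipid-bearing fibroblasts of the gas exchange region, were lower in hypercapnia. Of 19 measured markers 6 fell, none rose, and 16 had a negative log2 fold change. Gyg, the primer of glycogen synthesis, fell from 568 ± 39.8 to 294 ± 17.4 CPM (-0.95 ± 0.11), Col13a1 from 618 ± 66.7 to 333 ± 22.6 CPM (-0.89 ± 0.12), Fgfr4 from 381 to 246 CPM and the lipoprotein lipase gene Lpl from 112 to 63.8 CPM. Limch1 (-0.57) and Npnt (-0.44), chosen after their values were seen, fell too. Without M2 only Gyg of the 6 was called (adjusted p of 0.0638 for Col13a1, 0.126 for Fgfr4, 0.0574 for Lpl, 0.153 for Limch1 and 0.26 for Npnt), and likewise without M5 (0.0618, 0.124, 0.0795, 0.186 and 0.257). Without M6 Fgfr4 (0.0664), Lpl (0.0902), Limch1 (0.135) and Npnt (0.155) were lost, and Limch1 and Npnt also without M1 (0.0861 and 0.101) or M3 (0.0592 and 0.054). Npnt was lost with RLE factors (0.0521) and the stricter filter (0.0562) too. Tcf21, a transcription factor of these cells, had a log2 fold change of -0.44 with an adjusted p of 0.101. The list was called lower (camera adjusted p = 1.5e-09, 0.16 with an estimated correlation), and fry, which tests the list on its own, gave an adjusted p of 0.00921. Of 20 markers of adventitial fibroblasts, which surround airways and large vessels, Il33, an alarmin cytokine, rose (1.07 ± 0.21) and 19 did not pass. The call of Il33 was lost without M1 (adjusted p = 0.0927), M2 (0.0588), M3 (0.0655), M5 (0.195) or M6 (0.143), and with the endothelial covariate (0.88 ± 0.25), where its SE widened. Pi16 (0.69 ± 0.22), Col14a1 (0.53 ± 0.16) and Ly6a (0.53 ± 0.15) did not pass over all genes. Camera called the adventitial list higher (adjusted p = 0.00169, 0.671 with an estimated correlation, 0.27 by fry). The endothelial marker level was also higher in these libraries (7.32 against 6.29 log2 CPM).

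**Figure D4:**
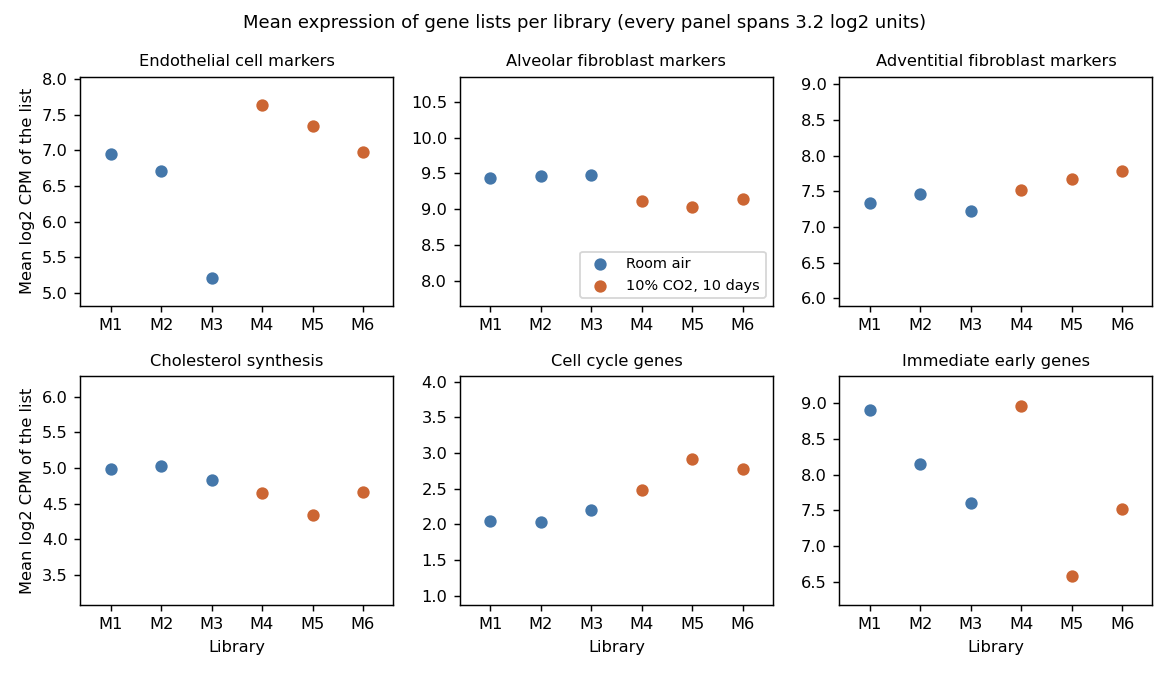
Mean log2 CPM (y axis) of 6 gene lists in each library (x axis, M1 to M3 room air in blue, M4 to M6 hypercapnia in orange), 1 panel per list. The alveolar list was lower in every hypercapnia library, the endothelial markers varied most among the room air libraries, and immediate early genes varied within both groups.

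Markers of other cell types were measured in the same libraries. All 18 measured endothelial markers had a positive log2 fold change, with a median of 0.88, and none passed the test. Pecam1 stood at 169 ± 101 CPM in room air and 308 ± 81.7 CPM in hypercapnia (0.87 ± 0.41, adjusted p = 0.437). The mean level of the list was 6.95, 6.71 and 5.22 log2 CPM in M1, M2 and M3, and 7.64, 7.34 and 6.98 in M4, M5 and M6. Camera called the list higher (adjusted p = 7.65e-12, 0.671 with an estimated correlation, which was itself 0.916). Airway epithelial markers were not called (adjusted p = 0.0714), with Scgb1a1 at 363 ± 112 and 223 ± 89.0 CPM, nor were alveolar type 2 cell markers (adjusted p = 0.404). Camera called neither pericyte (adjusted p = 0.12), macrophage (0.336), neural (0.502) nor mesothelial markers (0.569). Lymphocyte and red blood cell markers had no tested gene.

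Of 14 measured Notch pathway genes 2 rose, Dll4, a Notch ligand of arteries and sprouting vessels (1.33 ± 0.21, 21.3 to 53.5 CPM), and the Notch target Hey1 (1.0 ± 0.20, 29.6 to 59.2 CPM), and 12 did not pass. Camera called the list higher (adjusted p = 9.36e-05, 0.671 with an estimated correlation, 0.296 by fry). With the endothelial level as a covariate the adjusted p of the list was 0.763 and the call of Hey1 was lost (0.57 ± 0.17) while Dll4 was still called (0.91 ± 0.19, adjusted p = 0.037), and without M3 and M4 the list was not called (0.0897). Over libraries within groups, both genes varied with the endothelial level (correlation of 0.95 for Dll4 and 0.985 for Hey1). Both genes lost their calls without M2 (0.109 for Dll4 and 0.175 for Hey1), M5 (0.0743 and 0.157) or M6 (0.0793 and 0.134), and Hey1 also without M4 (0.0872). Cell cycle genes were also called higher as a list (adjusted p = 0.00162, 0.521 with an estimated correlation, 0.191 by fry), with 20 of 21 log2 fold changes positive and none past the test. Their levels were low, as for Cdc20 at 0.824 and 3.60 CPM.

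Camera called genes of cholesterol synthesis lower as a list at its preset correlation (adjusted p = 1.47e-08), and neither camera with an estimated correlation (0.668) nor fry (0.231) did. Of 24 measured members 2 fell and 22 did not pass. Insig1, which holds back the sterol sensor, fell from 149 ± 14.2 to 80.4 ± 20.2 CPM (-0.89 ± 0.17, and -0.83 ± 0.20 with the endothelial covariate, where its call was lost). That call was also lost without M1 (0.0567), M2 (0.22), M4 (0.0648) or M5 (0.121). In the hypoxia and glycolysis list Pfkp, a phosphofructokinase, fell (-0.89 ± 0.12) and so did Adm, the vasodilator peptide adrenomedullin (-1.24 ± 0.23), and 20 of 22 members did not pass. Neither was called without M2 (adjusted p = 0.0602 for Pfkp and 0.201 for Adm), and the call of Adm was also lost without M5 (0.0963) or M6 (0.134) and with robust dispersion (0.101). That list was called lower (camera adjusted p = 0.00169, 0.671 with an estimated correlation, 0.27 by fry), and not without M2 (0.0593) or M5 (0.106). Both lists were also called when M1, M2 and M4 were set against M3, M5 and M6 (adjusted p of 0.00123 and 0.00639), a split in which immediate early genes also differed (2.9e-44), and both were still called between the groups with the immediate early level as a covariate (1.17e-06 and 0.0181). Angptl4, a secreted inhibitor of lipoprotein lipase in the glucocorticoid-responsive list, fell from 320 ± 55.1 to 143 ± 19.5 CPM (lost without M5, adjusted p = 0.0558), and the other 20 measured members of that list did not pass. Of 17 carbonic anhydrases and acid-base transporters 0 passed over all genes, and the list was not called (adjusted p = 0.394).

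Genes that respond to tissue handling differed between libraries of the same group. The mean level of the immediate early genes was 8.91, 8.15 and 7.60 log2 CPM in M1, M2 and M3, and 8.97, 6.59 and 7.52 in M4, M5 and M6. None of their 24 measured members passed. The list was called lower in hypercapnia (camera adjusted p = 0.0241, 0.807 with an estimated correlation), and not without M1 (0.579), M5 (0.969) or M6 (0.156). Heat shock chaperones were also called lower (adjusted p = 0.00193, 0.688 with an estimated correlation), and not without M1 (0.114) or M5 (0.106). The share of mitochondrial counts was 1.1% in M3 and between 0.688% and 0.94% in the other libraries. With the immediate early level as a covariate, chosen after seeing the data, 264 genes were called, and all 159 were among them.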

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

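The covariate fits and the fit without M3 and M4 were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because the labels give the groups no shared replicate numbers. In every alternative the 159 changed genes kept their direction. Leaving out libraries could hardly turn it, since the libraries of the groups did not overlap in any of the 159. The number of changed genes depended on the settings, and no cause was tested. It was 756 with no filter on low counts, 436 by DESeq2, 255 with robust dispersion, 295 at an adjusted p under 0.1, 57 with at least 2-fold change, 264 with the immediate early level as a covariate and 388 without M3 and M4. With 1 library left out it ran from 24 (without M2) to 148 (without M4), with 27 without M5 and 42 without M6. With the endothelial level as a covariate it was 164, of which 90 were among the 159. The number of called Wnt ligands, 1 with all libraries, was 2 with no filter, 2 by DESeq2, 2 without M3 and M4, 0 with the endothelial covariate and 0 to 1 with 1 library left out. The number of called lists, 11 at the preset correlation, was 0 with an estimated correlation, where 47 lists were tested and 3 had an unadjusted p under 0.05, 1 by fry in a single direction and 28 by fry in either direction, 18 with the endothelial covariate and 8 (without M2) to 15 (without M4) with 1 library left out.

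Of 58 changed genes, those named by the rule, changed list members and Fendrr, Vipr2 and Col27a1, over 17 alternatives each, 803 values stayed past the threshold, 183 did not and 0 changed direction. Clmp, Col5a3, Colq, Eln, Fendrr, Gja5, Gyg, Igfbp3, Ltbp2, Npas2, Per2, Serpina3c, Spon2 and Vipr2 stayed past it in all 17. The 58 were picked as changed in these same data, without overlap between groups, so kept directions are no separate support. Without M2, 41 of the 58 were lost, without M5 38, without M6 32 and with the endothelial covariate 17. A lost call alone does not show a smaller effect, as in the clock genes without M2. Directions turned only where no call was made, apart from the endothelial list itself once its own level was the covariate (adjusted p = 0.934). The log2 fold change of Wnt5b turned to 0.0065 with library size only and 0.0616 without M3 and M4, and ran from -0.375 (without M5) to 0.0848 (without M4) with 1 library left out, above 0 also without M2 or M6. That of Wnt4 turned to 0.0257 with library size only, and ran from -0.22 (without M5) to 0.0981 (without M2), above 0 also without M4 or M6. The secreted Wnt modulators turned with the stricter filter (adjusted p = 0.886), by fry (0.894) and with the endothelial (0.978) or immediate early covariate (0.931). The Wnt receptors turned by ranks (0.965), without M3 (0.741), M4 (0.999) or M5 (0.808), with 0.589 to 0.999 over the libraries left out, with the endothelial covariate (0.31) and without M3 and M4 (0.676). The beta-catenin targets turned with the endothelial covariate (0.465) and without M3 and M4 (0.827).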

Other observations

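Apart from the test of Usp2 and Wee1, the tests of explanations in this part were chosen after the results were seen. Among changed genes outside the groups described so far, chosen after their values were seen, Fendrr, a long noncoding RNA of lung mesenchyme, rose from 27.1 ± 4.53 to 66.0 ± 7.21 CPM (SD, n = 3, log2 fold change 1.29 ± 0.16, edgeR adjusted p = 0.00527), and Vipr2, a receptor for vasoactive intestinal peptide, fell from 193 ± 11.1 to 73.4 ± 9.77 CPM (-1.40 ± 0.13, adjusted p = 0.000848). From the lists, Gsta3, a glutathione transferase, rose (0.78 ± 0.12), as did the proteoglycan gene Aspn (0.97 ± 0.19), while the adhesion molecule Vcam1 (-0.57 ± 0.10), the proteoglycan Prelp (-0.52 ± 0.11, 9.68% of its exonic bases shared with another gene model), the interferon-stimulated gene Ifit2 (-0.57 ± 0.11) and Upk1b (-0.73 ± 0.13) fell. With the endothelial covariate the call of Upk1b was lost with a smaller fold (-0.54 ± 0.14), and those of Aspn (0.83 ± 0.23), Vcam1 (-0.54 ± 0.13) and Ifit2 (-0.60 ± 0.14) were lost with folds that moved by less than their SE while the SE widened. Left out 1 at a time, each of the 6 libraries ended the calls of Ifit2 (adjusted p of 0.0569 to 0.185) and Upk1b (0.0539 to 0.164). So did each but M4 for Vcam1 (0.051 to 0.18), each but M1 for Aspn (0.0691 to 0.201), M1, M2, M5 or M6 for Prelp (0.0924, 0.259, 0.186 and 0.143) and M2, M5 or M6 for Gsta3 (0.126, 0.0795 and 0.0664). Ifit2 was lost with library size only (0.0584) and Aspn without M3 and M4 (0.0665). Fendrr and Vipr2 were called in all 17 alternatives. As lists, interferon-stimulated genes (camera adjusted p = 0.866), TGF-beta and BMP genes (0.856), NF-kB genes (0.138), oxidative phosphorylation (0.336), ribosomal proteins (0.229) and contractile genes (0.169) were not called.

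The 6 libraries can be split into 3 and 3 in 10 ways, the real split included, too few for a share under 0.05. The real split gave 159 genes and the highest of the other splits 5, so the real split was the 1 of the 10 to reach its count. For Wnt ligands the real split gave 1 and the highest other 0, again 1 of 10. For gene lists, 7 of the 10 splits, the real one included, gave at least the real 11, and the split of M1, M2 and M4 from M3, M5 and M6 gave 24, which points to a structure of the samples apart from the groups. In that split the immediate early genes (camera adjusted p = 2.9e-44) and heat shock chaperones (1.37e-19) had the smallest p, and the cholesterol synthesis (0.00123), endothelial (0.00184), hypoxia and glycolysis (0.00639), adventitial (0.00762) and cell cycle (0.0193) lists, all called between the real groups, were called there too. The second principal component, with 29.6% of the variance, put the same libraries on either side of 0.

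The endothelial markers, higher in hypercapnia, varied together from library to library. After removing group means, the median correlation between the 18 markers was 0.98, against a 95th percentile of 0.278 for random gene lists matched on expression. This is consistent with a varying amount of endothelial cells or their RNA in the sorted samples, with Pecam1 at 169 and 308 CPM although the sort selects PDGFRA. A smaller share of fibroblasts would raise the markers of every other cell type alike. Those of airway epithelium differed from the endothelial change by 1.47 (SE 0.719) on the log2 scale, too little for 3 libraries per group to decide. Among the tested lists of other cell types, only airway epithelium had a lower mean in hypercapnia (-0.441). Macrophage (0.695), pericyte (0.363), neural (0.235), mesothelial (0.215) and alveolar type 2 (0.191) means were higher and were not tested against the endothelial change. The group difference in the endothelial mean was 1.03 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give), so more endothelium in the lungs of exposed mice cannot be told apart from uneven sorting.

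Clock genes changed in both directions, as a later clock phase may bring. This was tested on Usp2 and Wee1, clock-controlled genes outside the list, with the prediction written before their values were seen. Both were higher by more than their SE, 2 of 2, at 1.16 ± 0.29 and 1.19 ± 0.28 (adjusted p = 0.0972 and 0.0848, and with the endothelial covariate log2 fold changes of 0.60 and 0.78 and adjusted p of 0.294 and 0.223), so the main fit called neither. Both were called by DESeq2 (0.00309 and 0.00493), with no filter on low counts (2.22e-07 and 4.4e-05) and with the immediate early covariate (0.00368 and 0.0397), and Wee1 also by limma-voom (0.0395), with robust dispersion (0.0387) and without M1 (0.0139). A rise by more than the SE is a weak criterion, and both genes were predicted to move with the Per genes, already seen higher. Their rise therefore cannot separate a later phase from another change of the clock. The endothelial covariate takes its slope from the spread within groups. That spread was larger in room air (SD 0.94, with M3 lowest at 5.215 log2 CPM) than in hypercapnia (SD 0.332). Within that limit, endothelial RNA as the whole cause is argued against. With the covariate, 7 of the 9 changed clock genes stayed past the threshold. The other 2, Cry1 (1.15 ± 0.20 before and 1.04 ± 0.27 after) and Clock (-0.84 ± 0.16 and -0.82 ± 0.20), lost their calls as the SE widened. A part for it stays open, since Per2 went from 1.62 ± 0.18 to 1.26 ± 0.16 and the call of the clock list was lost with the covariate (camera adjusted p = 0.688) and without M3 and M4 (0.341). Whether CO2 shifted the clock or the groups were collected at different hours cannot be told apart, because the labels give no hour, and within a group Per2 differed by up to 0.79 log2 units against 1.62 between groups. A difference in hour would bear on every gene compared between the groups, not on the clock genes alone.

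Camera at its preset correlation called alveolar fibroblast markers lower and adventitial markers higher. With an estimated correlation neither call held (adjusted p of 0.16 and 0.671), fry called the alveolar list (0.00921) and not the adventitial one (0.27), and only 1 of the 20 adventitial markers passed the test. Dilution of all fibroblast transcripts by RNA of other cells would lower both alike if those cells carried neither list's transcripts, which was not tested. The difference between the lists was -0.69 (SE 0.106) on the log2 scale. The pair was picked because camera called the lists in opposite directions, so this difference cannot decide on dilution. A trend with the endothelial level as the whole cause is argued against, within the limit of the covariate given above. With that covariate 6 of the 6 changed alveolar markers stayed past the threshold, although without M2 or M5 only Gyg of the 6 was called. A different mix of fibroblast subtypes in the sorted cells and a change of expression within alveolar fibroblasts cannot be told apart here, since the alveolar markers had a median correlation of 0.0191 over libraries within groups, which excludes neither.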
